A study of Mus musculus with 9 samples.

How the data were processed

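Total RNA from mouse kidneys was measured on 9 Affymetrix arrays after labelling as biotinylated cRNA. The labels give 3 groups of 3 arrays: uninfected kidney (CTL, replicates 1, 2 and 4), kidney infected with Staphylococcus aureus in the acute phase (T2, replicates 1, 3 and 4) and in the persistent phase (T28, replicates 1, 6 and 7). The labels do not state the unit of time behind T2 and T28. The titles of all 3 control arrays carry the T28 time point, and no separate control for T2 was used here. Differences of T2 from the controls or from T28 therefore cannot be told apart from differences between time points or collections. Whether each array came from a separate animal is not stated, so the p-values measure the spread between these samples only. The replicate numbers were not taken as pairs.

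The deposited values are log2 probe set signals, 1 column per array, and the submitters' processing notes name RMA without a version. Whether every step of RMA and its defaults were used is not stated. The range of the values on each array and the nearly equal array medians were checked before use. No further normalization was applied. The table held 45101 probe sets, of which 64 were control probe sets. Gene symbols came from the platform annotation: 34945 probe sets carried 1 symbol, 932 carried several, and 9160 carried none or were not in the annotation. Of the probe sets with 1 symbol, 34741 had a gene identifier found in the gene table of the GRCm38.p6 assembly, which changed 0 symbols. Each gene was represented by the probe set with the highest mean over the 9 arrays, which mattered for the 9010 genes with more than 1 probe set and left 18193 genes. No filter on signal was applied, and no detection calls were used, so the number of arrays limits the precision and low signals were not separated from background. After the data were seen, the highest signal of 3 Y-linked genes (4.46), on arrays that were all high in Xist, was taken as a level that background can reach. Changes of named genes from a group mean at or below it are called lower bounds, since such a mean may be background. That level was a single signal, of Kdm5d on CTL replicate 1. The other Y-linked signals reached at most 4.17, and those of Eif2s3y 3.56. A mean below the level is therefore not shown to be background. Some probe sets, those of immunoglobulin and histocompatibility genes among them, can share sequence with related genes, so that a value may include signal from a relative.

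Differential expression was tested with limma 3.58.1 in R 4.3.3, in 1 fit of the 3 group means over the 9 arrays with moderated variances (6 residual and 5.12 prior degrees of freedom). Fold changes are given on the log2 scale with the moderated standard error (SE), with n = 3 arrays per group. The median residual SD was 0.21 and the median SE of a difference 0.17. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were T2 against CTL, T28 against CTL, T28 against T2, and a moderated F test of any difference among the 3 groups. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so genes were not tested one by one in that way. On simulated data of the same size, with 200 changed genes in each of 5 runs, the fit found between 71% and 75% of the genes changed 2-fold. It found between 97% and 98.2% of those changed 4-fold, with 3.1% to 6.4% false calls and 0 calls of the wrong sign. Each simulated gene had the same spread in all groups, unlike the real arrays, and genes were drawn independently.

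Gene lists for cell types, immune responses, kidney segments and metabolism (36 lists, 677 of 753 memberships measured) were fixed before the data were examined, as were the comparisons, the alternatives below and the rule for naming genes. The 35 lists with at least 5 measured members were tested with camera, a competitive test that compares a list with all other genes, at its preset correlation between genes of 0.01, with adjustment over the lists within a comparison. Camera with a correlation estimated from the data and fry, a test of a list on its own, were run beside it. With 3 arrays per group the estimated correlation is itself imprecise. In the simulated data, 5 of 5 shifted lists were called in each comparison, and 1, 0 and 0 of 150 unshifted lists. The simulated genes were uncorrelated, so these rates do not cover lists whose genes move together. In the real data the estimated correlation ran from -0.11 for the erythroid list to 0.874 for the adrenal list. Some genes stand in more than 1 list, for example Lcn2 and Timp1.

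Genes were named by the following rule: in each comparison, the 12 called genes with the largest rise and the 12 with the largest fall, without clone and model names; up to 4 called members of each list in either infected group; the same choice, up to 6 per direction, among genes called in 1 phase and not the other and called between the phases; and a set of genes of interest, called or not, from cytokines to tubule transporters. One item of that set is not reported here. One kappa variable gene among those with the largest rise is described without its symbol. Genes named outside the rule are marked as chosen after their values were seen.

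The alternatives were quantile normalization, centring of each array on its median, a filter to genes at or above the median level, all probe sets or the mean of a gene's probe sets, an intensity trend or a robust prior in the variance model, array weights, a fit of only the groups compared, an added threshold of 2-fold, the replicate number as a fixed block or as a random block (with statmod 1.5.0), and leaving out each array in turn. Replicate numbers 2, 3, 6 and 7 each stood on 1 array, so the fixed block fitted those arrays exactly and drew only on the others. In that fit T28 rests on replicate 1 alone, an array high in adrenal gland markers, and T2 and CTL on replicates 1 and 4. Its results are limited accordingly. Leaving out 2 arrays high in adrenal gland markers was added after the data were seen. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.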

Results

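Transcript levels were measured in 9 mouse kidney samples, 3 uninfected (CTL), 3 in the acute phase (T2) and 3 in the persistent phase (T28) of infection with Staphylococcus aureus, to find host genes whose expression changes in each phase. Median log2 signals lay between 5.26 and 5.34 on the 9 arrays. The control arrays were close to one another: 4, 10 and 12 genes lay at least 2-fold from the control mean, against 635, 626 and 382 genes on T2 replicates 1, 3 and 4, and 1351, 1091 and 325 genes on T28 replicates 1, 6 and 7. The first principal component held 42.1% of the variance and set T28 replicates 1 and 6, at 52.6 and 49.5, apart from the controls, at -19.6 to -18.6. T28 replicate 7 lay between them at 10.6. The second component, 24.2% of the variance, separated T2, at -32.7 to -18.5, from the controls, at 24.65 to 26.1. Xist, a transcript of the inactive X chromosome, had log2 signals of 12.34 to 12.59 on all 9 arrays, and the Y-linked genes Kdm5d, Eif2s3y and Uty had at most 4.46. The 3' minus 5' signal gap of Gapdh, a sign of RNA quality, was larger at T28 (0.283 ± 0.089, SD, n = 3) than in the controls (-0.024 ± 0.087), with 0.373, 0.279 and 0.196 on T28 replicates 1, 6 and 7 and at most 0.067 on the controls. The actin gap was 0.946 ± 0.089 at T28 and 0.873 ± 0.092 in the controls, a difference within the spread. CTL replicate 4 and T28 replicate 1 carried high signals of adrenal gland transcripts: Cyp11b1, an enzyme of corticosteroid synthesis, stood at 9.51 and 9.74 there and at 4.35 to 5.85 on the other arrays, and Hsd3b1, an enzyme of steroid synthesis, at 11.49 and 11.55 against 4.76 to 8.17. These adrenal genes were chosen after their values were seen.

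In the acute phase, the largest rises included genes of neutrophils, acute phase proteins and inflammatory mediators. Transcripts of the neutrophil calcium-binding proteins S100a8 and S100a9 rose 52.5-fold and 51.9-fold (log2 change 5.71 ± 0.53 and 5.70 ± 0.56, SE, n = 3 per group). Lcn2, an iron-sequestering protein released by neutrophils and injured tubules, rose 45.8-fold (5.52 ± 0.70), the neutrophil chemoattractant Cxcl2 45.4-fold (5.51 ± 0.58), and the cytokine Il6, an inducer of acute phase proteins, 27.1-fold (4.76 ± 0.47). The 3 fibrinogen chains Fga, Fgb and Fgg rose 21.4-fold, 29.7-fold and 22.1-fold, and Havcr1, a membrane protein of injured proximal tubules, 19.3-fold (4.27 ± 0.64). Aplnr, the apelin receptor of endothelium, fell 15.6-fold (-3.96 ± 0.49), and the clock output gene Dbp fell 9.20-fold (-3.20 ± 0.46).

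The other genes among the 12 largest rises at T2 were Chil3, a chitinase-like protein of macrophages and neutrophils (5.95 ± 0.41, adjusted p = 4.23e-05), and the serum amyloid genes Saa3 and Saa1 (4.90 and 4.45). Below Aplnr and Dbp, the largest falls were in Dio1, a deiodinase that activates thyroid hormone (-2.98), the transporter Slc22a30 (-2.88), Thrsp, a regulator of lipid synthesis (-2.85), the sodium-calcium exchanger Slc8a1 (-2.70), Hdc, which makes histamine (-2.60), Inmt, an indole methyltransferase (-2.53), Scd1, a fatty acid desaturase (-2.39 ± 0.17), and the genes Hsd3b2, Clec2h and Ces1e (-2.37, -2.30 and -2.25). All 24 of the genes named for the largest changes kept their call without any single array and under quantile normalization, median centring and the mean of a gene's probe sets. The control means of Chil3 (3.76), Cxcl2 (4.22) and Il6 (3.01) were no higher than the highest Y-linked signal, 4.46. Their changes at T2 are therefore treated as lower bounds, and their order among the largest rises is not exact. The same limit applies to the T2 changes of Arg1, Clec4e, Cxcl3 and Mmp8 given below, with control means of 3.66, 3.89, 3.08 and 4.44.

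Of 23 acute phase genes measured, 15 were higher and 1 lower at T2, and 17 and 1 when adjusted over the list alone. Haptoglobin (Hp) rose by 3.73 ± 0.45 and Socs3, a feedback inhibitor of cytokine signalling, by 3.29 ± 0.37. The gene that fell was Orm1, an acute phase glycoprotein (-2.18 ± 0.42, adjusted p = 0.0160), named after its value was seen. The median log2 change of the list was 1.91, with camera adjusted p = 5.74e-23, and adjusted p = 0.102 with an estimated correlation. Among 20 neutrophil genes, 6 were higher and 1, Hdc, lower (9 and 1 adjusted over the list alone), with the collagenase Mmp8 at 2.87 and the pattern receptor Clec4e at 2.30. The neutrophil test gave adjusted p = 2.30e-09, and adjusted p = 0.301 with an estimated correlation. The macrophage list had 4 of 23 genes higher (6, and 1 lower, adjusted over the list alone), among them the endotoxin co-receptor Cd14 (3.40) and the arginine-degrading enzyme Arg1 (2.40), at adjusted p = 1.17e-07 (adjusted p = 0.367 with an estimated correlation).

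Inflammatory mediators and antigen presentation were higher as well. Chemokines had 4 of 28 genes higher, Cxcl3 (4.17) among them, and 13 higher and 1 lower adjusted over the list alone. The chemokine test gave adjusted p = 2.67e-07, and adjusted p = 0.367 with an estimated correlation. Cytokines had 2 of 27 higher, Il6 and Il1b (2.04), and 7 adjusted over the list alone. The cytokine test gave adjusted p = 0.00426, and adjusted p = 0.367 with an estimated correlation. Interferon gamma response and MHC class II genes had 9 of 20 higher, such as the guanylate-binding protein Gbp6 (2.01), the peptide-exchange gene H2-DMb2 (1.93) and the GTPase Igtp (1.61), and 13 adjusted over the list alone. The interferon gamma test gave adjusted p = 1.80e-11, and adjusted p = 0.206 with an estimated correlation. MHC class I processing had 5 of 14 higher, with the class I heavy chains H2-K1 (1.66) and H2-D1 (1.56), and 10 adjusted over the list alone. The MHC class I test gave adjusted p = 1.25e-12, and adjusted p = 0.173 with an estimated correlation. Pattern recognition genes had 5 of 24 higher (8, and 1 lower, adjusted over the list alone), at adjusted p = 4.46e-05 and at adjusted p = 0.367 with an estimated correlation. Type I interferon response had 0 of 23 called members but a median of 0.31 (0 adjusted over the list alone). The type I interferon test gave adjusted p = 0.00151, and adjusted p = 0.367 with an estimated correlation. Complement also had 0 of 18 called (2 higher and 1 lower adjusted over the list alone), at adjusted p = 0.0241, which became 0.0509 without T2 replicate 3, and at adjusted p = 0.367 with an estimated correlation. The list of inhibitory receptors and immune regulation had 2 of 20 higher, Socs3 and Arg1, neither of them a receptor of lymphocytes (4 adjusted over the list alone). The immune regulation test gave adjusted p = 0.00149, and adjusted p = 0.165 with an estimated correlation. Endothelium and adhesion had 0 of 18 called, 3 higher adjusted over the list alone. The endothelium test gave adjusted p = 0.00104, and adjusted p = 0.102 with an estimated correlation.

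Injury and stress genes rose at T2. Kidney injury genes had 7 of 24 higher, with Krt20, a keratin of injured epithelium, at 3.50 ± 0.45 and the protease inhibitor Timp1 at 3.01 ± 0.48, and 14 adjusted over the list alone. The kidney injury test gave adjusted p = 3.69e-14, and adjusted p = 0.291 with an estimated correlation. Heat shock and ER stress genes had 8 of 20 higher, such as Chac1, a glutathione-degrading enzyme of the stress response (2.04), and the small heat shock protein Hspb1 (1.32), and 12 adjusted over the list alone. This list was called with the preset and with the estimated correlation (adjusted p = 3.69e-14 and 0.0178). Immediate early genes had 7 of 20 higher, with the transcription factors Fos (2.15), Egr1 (1.91) and Junb (1.53), and 11 adjusted over the list alone. The immediate early test gave adjusted p = 1.25e-12, and adjusted p = 0.165 with an estimated correlation. Coagulation and fibrinolysis had 5 of 17 higher (7, and 2 lower, adjusted over the list alone). The coagulation test gave adjusted p = 0.00308, and adjusted p = 0.347 with an estimated correlation. Glycolysis and hypoxia had 1 of 21 higher (3 adjusted over the list alone). The glycolysis test gave adjusted p = 0.0385, and adjusted p = 0.376 with an estimated correlation. The glycolysis call was lost without CTL replicate 2 (adjusted p = 0.0863) or T2 replicate 3 (0.118), and with the replicate number as a fixed block (0.205).

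Matrix and tubule genes moved both ways at T2, and adipose markers fell. Extracellular matrix genes had 5 of 30 lower, among them the collagens Col6a3 (-1.97 ± 0.26) and Col14a1 (-1.73 ± 0.15) and the collagen-binding proteoglycan Lum (-1.65 ± 0.20), and 4 higher, Timp1 among them; adjusted over the list alone, 12 were lower and 4 higher. The matrix test, in the lower direction, gave adjusted p = 0.00330, and adjusted p = 0.583 with an estimated correlation. Of the adipose markers, 3 of 8 were lower, such as the muscle and fat carbonic anhydrase Car3 (-1.90) and the fat hormone Adipoq (-1.72), and 5 adjusted over the list alone. The adipose test gave adjusted p = 0.000136, and adjusted p = 0.301 with an estimated correlation. The adipose score was -0.82, -1.22 and -1.23 on the T2 arrays and -0.37 to 0.18 on the controls. Proximal tubule genes moved both ways, 5 of 27 lower and 2 higher (7 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.195): the amino acid transporter Slc6a19 and the inositol oxygenase Miox fell (-1.45 and -1.42), and the monooxygenase Cyp4b1 and the sulfate transporter Slc13a1 rose (2.22 and 1.37). Loop of Henle and distal nephron had 2 of 15 lower, with the calcium-binding protein Pvalb at -2.19 (3 adjusted over the list alone; adjusted p = 0.0552). The water channel Aqp2 was the 1 of 17 collecting duct genes called higher (1.42; adjusted p = 0.0105), a call lost without CTL replicate 2 or T2 replicate 1 (adjusted p up to 0.0622); adjusted over the list alone 1 was higher and 1 lower, and the list was not called (adjusted p = 0.598).

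Metabolic lists moved apart. Steroid, bile acid and drug metabolism had 5 of 22 higher, such as Cyp2d9 (2.14), the fatty acid hydroxylases Cyp4a12a (1.97) and Cyp4a14 (1.83) and the vitamin D hydroxylase Cyp27b1 (1.87), and 6 higher and 1 lower adjusted over the list alone. The steroid and drug metabolism test gave adjusted p = 8.97e-05, and adjusted p = 0.301 with an estimated correlation. Fatty acid oxidation and peroxisome had 3 of 25 higher and 1 lower (5 and 2 adjusted over the list alone). The fatty acid oxidation test gave adjusted p = 0.000801, and adjusted p = 0.466 with an estimated correlation. Oxidative phosphorylation had 1 of 28 lower (1 adjusted over the list alone), with the list called lower at adjusted p = 0.00330 (0.0545 without T2 replicate 3 and 0.0900 with the fixed block; adjusted p = 0.577 with an estimated correlation). The cell cycle list was lower with 1 of 27 genes called (1 adjusted over the list alone). The cell cycle test gave adjusted p = 0.0160, and adjusted p = 0.466 with an estimated correlation. Lists of dendritic cells (0 of 13 called), T cells (0 of 18), NK and cytotoxic cells (1 of 13 higher), B and plasma cells (0 of 19), mast cells and eosinophils (0 of 13), erythroid cells (1 of 7 lower), adrenal gland (0 of 9), podocytes (1 of 10 higher) and ribosomal proteins (0 of 12) were not called at T2, with adjusted p of 0.825, 0.195, 0.868, 0.272, 0.907, 0.320, 0.138, 0.0820 and 0.620. Adjusted over the list alone, podocytes had 2 higher and the others the same counts as over all genes. The NK list had a median of -0.08 and a mean of 0.05, and the erythroid list a median of 0.01 and a mean of -0.25.

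At T2, limma called 664 of 18193 genes, 303 higher and 361 lower, of which 193 and 144 changed at least 2-fold. The count depended on single arrays: it was 242, 289 and 275 without CTL replicates 1, 2 and 4, 311 and 290 without T2 replicates 1 and 3, and 1012 without T28 replicate 7. It was 321, of which 303 were among the 664, without CTL replicate 4 and T28 replicate 1, the arrays with adrenal transcripts. The excess of lower calls turned into an excess of higher ones without CTL replicate 4 (146 higher and 129 lower), T2 replicate 1 (158 and 153), T2 replicate 3 (147 and 143) or both arrays with adrenal transcripts (169 and 152).

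**Figure D1:**
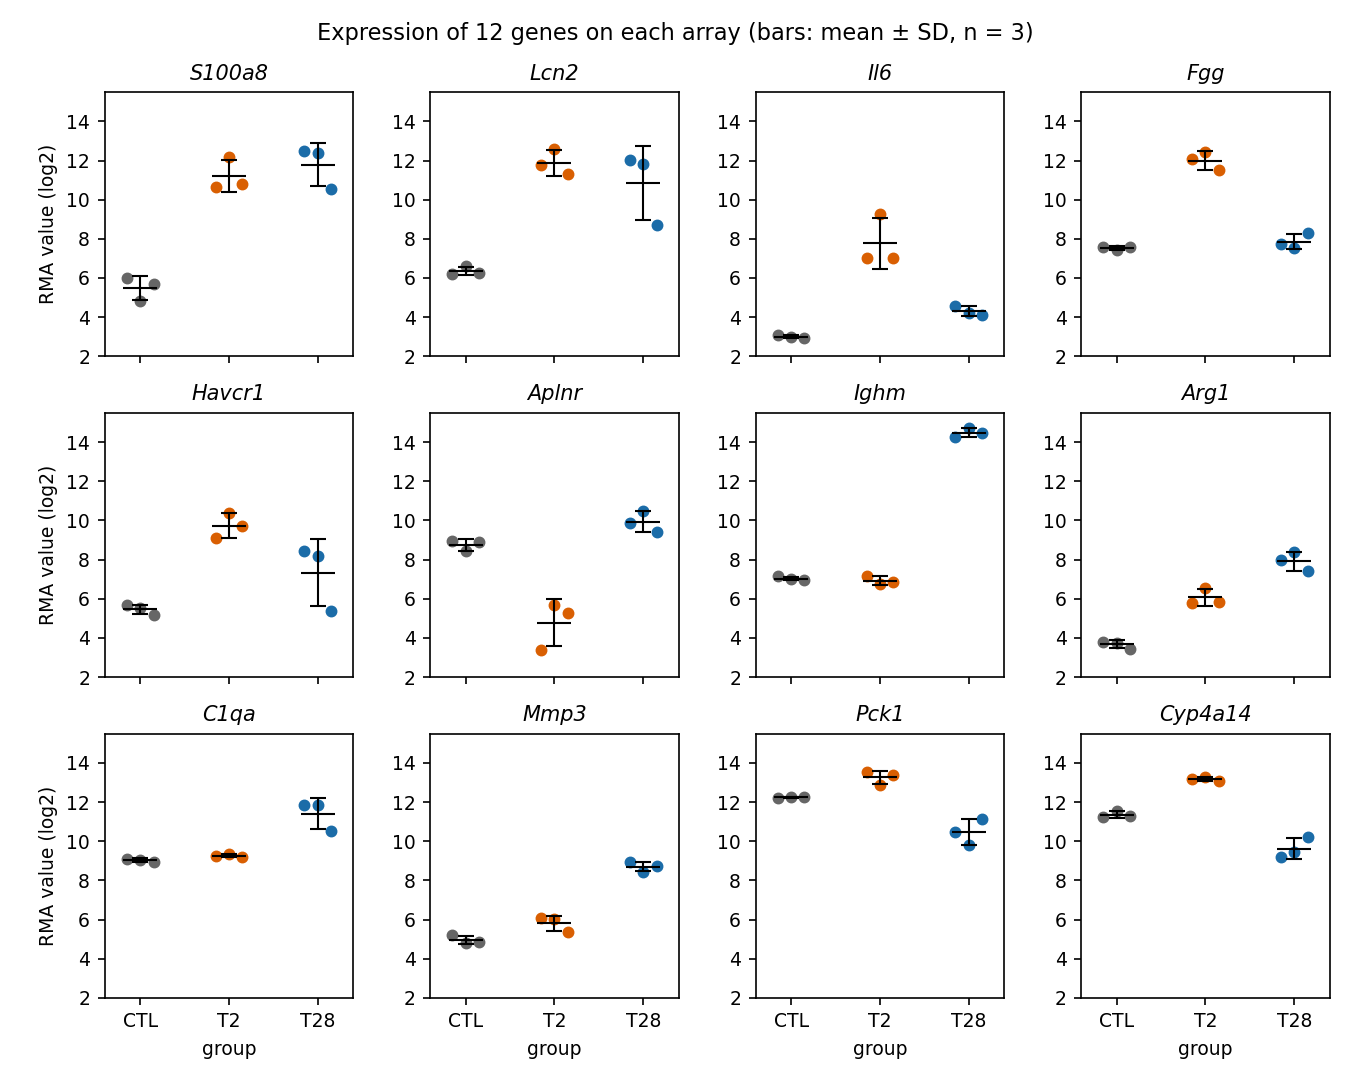
Log2 signal of 12 genes on each of the 9 arrays, as points in replicate order within CTL, T2 and T28, with the mean and SD of each group (n = 3). S100a8, Lcn2 and Arg1 lie above the controls in both phases, Il6, Fgg and Havcr1 are highest at T2, and Ighm, C1qa and Mmp3 are highest at T28.

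In the persistent phase, the 12 largest rises included immunoglobulin genes and genes of neutrophils, acute phase proteins and chemokines. Ighm, the heavy chain of IgM, rose 174.0-fold (log2 change 7.44 ± 0.16, SE, n = 3 per group) and the kappa light chain Igk 86.7-fold (6.44 ± 0.49). Neutrophil genes were also high: S100a9 rose 96.4-fold and S100a8 78.4-fold (6.59 ± 0.56 and 6.29 ± 0.53). Slpi, an inhibitor of neutrophil elastase, rose 81.2-fold (6.34 ± 0.25), the monocyte chemoattractant Ccl8 24.9-fold (4.64 ± 0.56), and the matrix-degrading enzyme Mmp3 13.4-fold (3.75 ± 0.20). Ces2b, a carboxylesterase, fell 4.08-fold (-2.03 ± 0.25), and Pck1, the key enzyme of gluconeogenesis, fell 3.38-fold (-1.76 ± 0.28).

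Saa3 (5.87), Cxcl2 (5.25), Lcn2 (4.50) and the light chain genes Iglv1 (5.12) and Igkv8-30 (4.72) and a further kappa variable gene (4.87) completed the 12 largest rises. The 11 probe sets of Ighm all changed in the same direction, and signals of single immunoglobulin genes can include their relatives. After Ces2b, the falls that held without any single array included the bile acid reductase Akr1d1 (-1.98), the growth factor binding protein Igfbp3 (-1.79), the lipase-like Abhd3 (-1.75), the fatty acid hydroxylase Cyp4a14 (-1.73 ± 0.23) and the mitochondrial carrier Slc25a16 (-1.54). Sec14l3, Ninl, Slc22a4, Aqp4 and Clec2h were also among the 12 largest falls (-1.97, -1.74, -1.65, -1.54 and -1.53), and each lost its call without some single arrays, with adjusted p up to 0.0933, 0.128, 0.118, 0.125 and 0.103. The control means of Cxcl2 (4.22) and of the kappa variable gene given without a symbol (3.99) were no higher than 4.46, the highest Y-linked signal. Their changes are therefore treated as lower bounds. This also applies to the T28 changes of Arg1, Cxcl5, Mmp12 and Pou2af1 given below, with control means of 3.66, 3.22, 4.10 and 3.40.

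Several lists of immune cell markers rose at T28. Of 23 macrophage genes, 21 were higher (22 adjusted over the list alone), among them Arg1 (4.26 ± 0.26), the lysozyme gene Lyz2 (3.21 ± 0.28) and the membrane protein Ms4a7 (3.09 ± 0.41), with a median of 2.31. The macrophage test gave adjusted p = 7.04e-31, and adjusted p = 0.102 with an estimated correlation. Neutrophil genes had 9 of 20 higher (15 adjusted over the list alone). The neutrophil test gave adjusted p = 4.02e-14, and adjusted p = 0.139 with an estimated correlation. B and plasma cell genes had 11 of 19 higher, with the B cell coactivator Pou2af1 (4.29), the plasma cell chaperone Mzb1 (4.18) and the joining chain Jchain (4.09), and 16 adjusted over the list alone. The B and plasma cell test gave adjusted p = 5.85e-16, and adjusted p = 0.102 with an estimated correlation. Dendritic cell genes had 5 of 13 higher, such as the integrin Itgax (1.76) and the transcription factor Irf8 (1.30), and 6 adjusted over the list alone. The dendritic cell test gave adjusted p = 2.54e-06, and adjusted p = 0.102 with an estimated correlation. T cell genes had 3 of 18 higher, with the receptor chain Cd3g at 2.29 ± 0.40, and 6 adjusted over the list alone. The T cell test gave adjusted p = 7.23e-06, and adjusted p = 0.178 with an estimated correlation. NK and cytotoxic genes had 2 of 13 higher (3 adjusted over the list alone), with the chemokine Ccl5 at 2.19. The NK test gave adjusted p = 0.00370, and adjusted p = 0.140 with an estimated correlation. The call was lost without both arrays with adrenal transcripts (adjusted p = 0.0660). T28 replicate 7 was the lowest of the 3 in these scores: the macrophage score was 2.75, 2.82 and 1.63 on replicates 1, 6 and 7, and the B and plasma cell score 0.90, 1.74 and 0.77. The T cell score was 0.61, 0.60 and 0.07 there, and at most 0.04 on the controls. The NK score was 0.59, 0.19 and 0.07, and at most 0.03 on the controls. Replicate 7 thus showed little of the T cell and NK rises.

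Innate immune and antigen presentation genes rose at T28. Chemokines had 15 of 28 higher, with Cxcl5 at 3.78, and 21 adjusted over the list alone. The chemokine test gave adjusted p = 5.67e-16, and adjusted p = 0.139 with an estimated correlation. Pattern recognition had 15 of 24 higher, with the lectin receptors of microbial sugars Clec4n (3.56) and Clec7a (3.08) and the receptor Tlr1 (2.09), and 19 adjusted over the list alone. The pattern recognition test gave adjusted p = 5.67e-16, and adjusted p = 0.102 with an estimated correlation. Interferon gamma response and MHC class II had 13 of 20 higher, with H2-DMb2 (2.54), H2-DMa (2.24) and the invariant chain Cd74 (2.12), and 15 adjusted over the list alone. The interferon gamma test gave adjusted p = 6.37e-17, and adjusted p = 0.102 with an estimated correlation. MHC class I processing had 10 of 14 higher, with the class I transactivator Nlrc5 (2.05) and the proteasome subunit Psmb8 (1.61), and 14 adjusted over the list alone. The MHC class I test gave adjusted p = 1.29e-15, and adjusted p = 0.102 with an estimated correlation. Complement had 7 of 18 higher, with the C1q chains C1qa (2.38), C1qb (2.31) and C1qc (2.57) and the receptor C3ar1 (1.73), and 12 higher and 1 lower adjusted over the list alone. The complement test gave adjusted p = 1.86e-08, and adjusted p = 0.102 with an estimated correlation. Inhibitory receptors and immune regulation had 5 of 20 higher, with the checkpoint ligand Cd274 (1.57 ± 0.16) and the inhibitory receptor Btla (1.18 ± 0.20), and 9 higher and 1 lower adjusted over the list alone. The immune regulation test gave adjusted p = 1.51e-08, and adjusted p = 0.0548 with an estimated correlation. Acute phase genes had 7 of 23 higher (15 adjusted over the list alone). The acute phase test gave adjusted p = 3.71e-12, and adjusted p = 0.102 with an estimated correlation. Cytokines had 3 of 27 higher, with Il1b at 3.28 (4 adjusted over the list alone). The cytokine test gave adjusted p = 8.33e-05, and adjusted p = 0.184 with an estimated correlation. Type I interferon response had 1 of 23 higher and 1 lower (4 and 1 adjusted over the list alone), at adjusted p = 0.00906, which became 0.112 without T28 replicate 1, and at adjusted p = 0.365 with an estimated correlation. Immediate early genes had 4 of 20 higher, with Fos at 2.63, and 6 adjusted over the list alone. The immediate early test gave adjusted p = 6.36e-07, and adjusted p = 0.178 with an estimated correlation. Kidney injury genes had 6 of 24 higher, with the adhesion receptor Cd44 at 3.03, and 11 adjusted over the list alone. Havcr1 and Krt20, called higher at T2, were not among the 6. The kidney injury test gave adjusted p = 3.91e-07, and adjusted p = 0.287 with an estimated correlation. The kidney injury score was 1.09, 0.64 and 0.01 on T28 replicates 1, 6 and 7. Replicate 7 lay within the range of the controls, -0.05 to 0.04.

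Matrix and proliferation genes rose. Extracellular matrix genes had 13 of 30 higher, led by Mmp3, with Timp1 (3.16) and the metalloproteinases Mmp13 (3.11) and Mmp12 (2.34), and 23 adjusted over the list alone. The matrix test gave adjusted p = 8.32e-17, and adjusted p = 0.140 with an estimated correlation. The matrix score was 1.61 and 1.40 on T28 replicates 1 and 6 and 0.25 on replicate 7. Cell cycle genes had 6 of 27 higher, with the cyclin Ccna2 at 1.03 ± 0.17, and 17 adjusted over the list alone. The cell cycle test gave adjusted p = 2.53e-10, and adjusted p = 0.102 with an estimated correlation. Coagulation and fibrinolysis had 4 of 17 higher (7, and 3 lower, adjusted over the list alone). The coagulation test gave adjusted p = 0.0408, and adjusted p = 0.362 with an estimated correlation. This call was lost without CTL replicate 2 (adjusted p = 0.111) or T28 replicate 6 (0.241). With the replicate number as a fixed block it was also lost, but that fit rests T28 on replicate 1 alone.

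Proximal tubule, collecting duct and 3 metabolic lists were lower at T28. Proximal tubule genes had 4 of 27 lower and 0 higher, with Pck1 the largest, and 10 lower adjusted over the list alone, with a median of -0.46. The proximal tubule test gave adjusted p = 3.99e-08, and adjusted p = 0.255 with an estimated correlation. Collecting duct genes had 3 of 17 lower, with the intercalated cell transcription factor Foxi1 at -0.82 ± 0.13, and 5 adjusted over the list alone. The collecting duct test gave adjusted p = 1.01e-05, and adjusted p = 0.277 with an estimated correlation. Fatty acid oxidation and peroxisome had 5 of 25 lower (11 adjusted over the list alone), with a median of -0.46. The fatty acid oxidation test gave adjusted p = 1.84e-08, and adjusted p = 0.226 with an estimated correlation. Oxidative phosphorylation had 1 of 28 lower (1 adjusted over the list alone), with a median of -0.28. The oxidative phosphorylation test gave adjusted p = 5.81e-06, and adjusted p = 0.322 with an estimated correlation. Steroid, bile acid and drug metabolism had 3 of 22 lower and 1 higher, the hydroxylase Cyp7b1 (1.27), and 6 and 1 adjusted over the list alone. The steroid and drug metabolism test gave adjusted p = 0.000682, and adjusted p = 0.255 with an estimated correlation. On T28 replicates 1, 6 and 7 the proximal tubule score was -0.60, -0.66 and -0.13 and the fatty acid oxidation score -0.62, -0.76 and -0.12, beside the immune cell scores given above. In the other 3 lists replicate 7 lay within the range of the controls. The collecting duct score was -0.65, -0.59 and -0.02 (controls -0.09 to 0.06) and the oxidative phosphorylation score -0.42, -0.46 and -0.05 (controls -0.06 to 0.03). The steroid and drug metabolism score was -0.64, -0.56 and -0.06 (controls -0.07 to 0.07). Lists of mast cells and eosinophils (0 of 13 called), erythroid cells (1 of 7 higher), adipose (0 of 8), adrenal gland (0 of 9), loop of Henle and distal nephron (0 of 15), podocytes (0 of 10), endothelium and adhesion (4 of 18 higher), glycolysis and hypoxia (1 of 21 higher), heat shock and ER stress (1 of 20 lower) and ribosomal proteins (0 of 12) were not called, with adjusted p of 0.864, 0.568, 0.181, 0.855, 0.101, 0.910, 0.0784, 0.493, 0.341 and 0.752. Adjusted over the list alone, endothelium had 5 higher, glycolysis 2 higher, heat shock 5 higher and 1 lower, and the others the same counts. The adrenal list was called lower without T28 replicate 1 (adjusted p = 0.0473) and higher without CTL replicate 4 (0.0240).

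At T28, limma called 1002 of 18193 genes, 581 higher and 421 lower, of which 404 and 92 changed at least 2-fold. The fit gives each gene 1 spread for all groups, while the median SD was 0.235 at T28, 0.164 at T2 and 0.124 in the controls. With only the groups compared, 377 genes were called at T28 and 1301 at T2, which reverses the order of 1002 and 664. Which phase changed more genes is therefore not settled. The counts that follow are again from the fit of all groups. The count was 387, 312 and 339 without CTL replicates 1, 2 and 4, 447 and 605 without T28 replicates 1 and 6, and 2652, including 985 of the 1002, without T28 replicate 7. It was 162, including 155 of the 1002, without the arrays with adrenal transcripts. The excess of higher calls turned into an excess of lower ones among genes at or above the median level (394 higher and 593 lower) and without T28 replicate 7 (1248 and 1404). It also turned with the replicate number as a fixed block, a fit that rests T28 on replicate 1 alone.

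**Figure D2:**
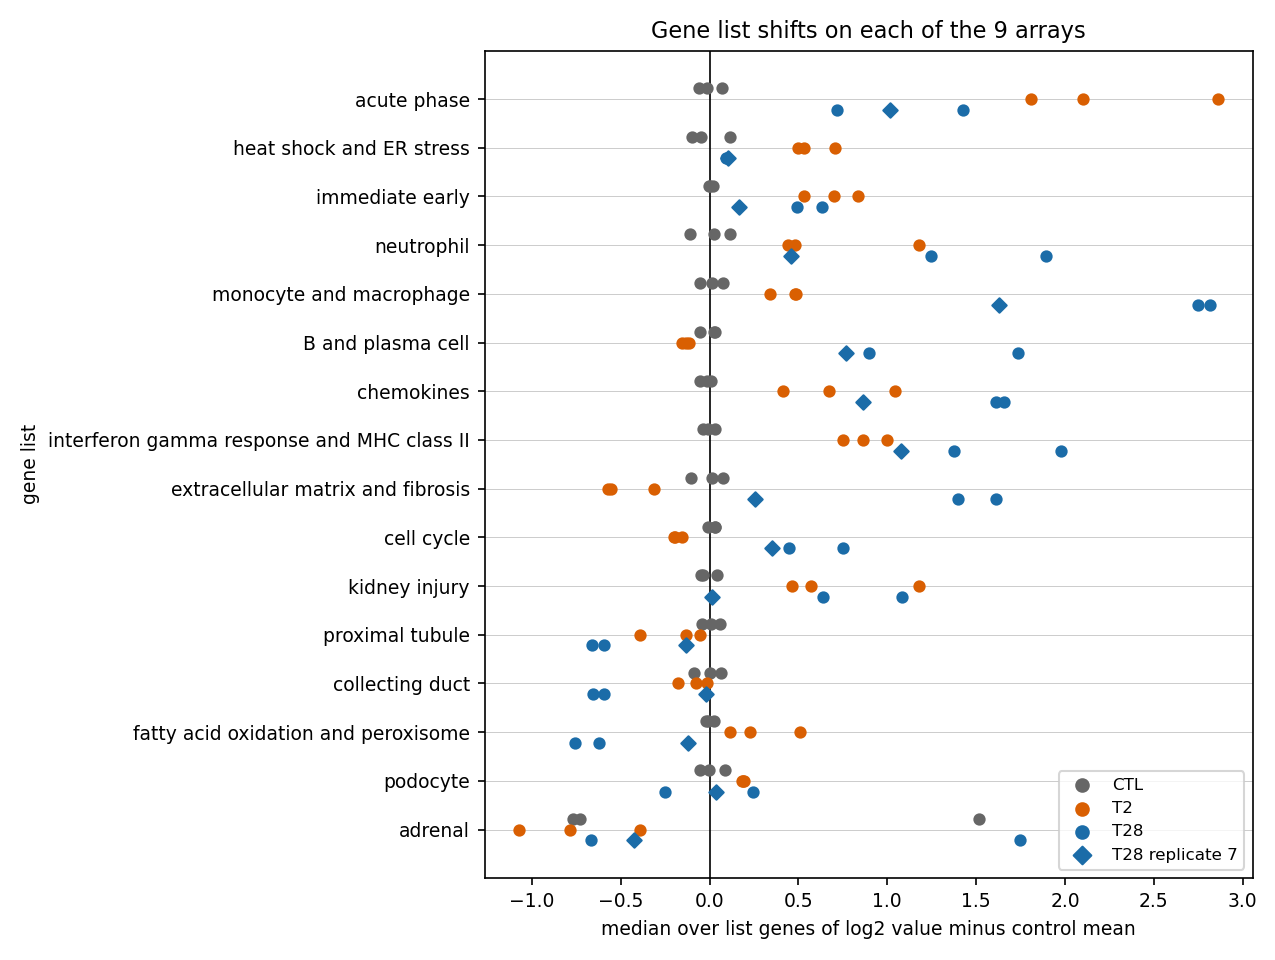
Score of 16 gene lists on each array, the median over list members of the log2 signal minus the control mean, with T28 replicate 7 drawn as a diamond. Macrophage scores reach 2.75, 2.82 and 1.63 at T28, and matrix scores lie at 1.61, 1.40 and 0.25. Adrenal scores are highest on T28 replicate 1 (1.75) and CTL replicate 4 (1.52).

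The phases were compared directly to ask which genes differ between acute and persistent infection. With no control titled T2, such a difference cannot be told apart from one between the time points that is unrelated to infection. Immunoglobulin genes were higher at T28, with Ighm up 186.9-fold and Jchain 44.7-fold over T2 (7.55 ± 0.16 and 5.48 ± 0.45, SE, n = 3 per group), as were Slpi (36.7-fold) and Aplnr (35.4-fold; 5.15 ± 0.49), a gene that fell at T2. The collagens Col1a1 and Col3a1 were 8.21-fold and 8.24-fold higher at T28 (3.04 ± 0.46 and 3.04 ± 0.36). The fibrinogen chains Fgg and Fga were 17.6-fold and 17.0-fold lower (-4.14 ± 0.24 and -4.09 ± 0.19), Il6 11.04-fold lower (-3.47 ± 0.47), and Cyp4a14, which rose at T2 and fell at T28, 11.8-fold lower (-3.56 ± 0.23). The T28 mean of Il6, 4.30, was no higher than the highest Y-linked signal, 4.46. Its difference is therefore treated as a lower bound in size, although the mean is not shown to be background. Pdk4, a kinase that restrains glucose oxidation, and Angptl4, a lipase inhibitor, were lower by -3.35 ± 0.25 and -3.02 ± 0.25.

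Several immune cell lists and the matrix list were higher at T28 than at T2. Macrophage genes had 17 of 23 higher and 1 lower, with Ms4a7 at 4.32 and Lyz2 at 2.63 (18 and 2 adjusted over the list alone). The macrophage test gave adjusted p = 1.34e-14, and adjusted p = 0.186 with an estimated correlation. B and plasma cell genes had 12 of 19 higher (17 adjusted over the list alone). The B and plasma cell test gave adjusted p = 1.62e-16, and adjusted p = 0.132 with an estimated correlation. T cell genes had 6 of 18 higher, with Thy1 at 3.06 and Cd3g at 2.82 (9 adjusted over the list alone). The T cell test gave adjusted p = 7.20e-07, and adjusted p = 0.186 with an estimated correlation. Dendritic cell genes had 6 of 13 higher (7 adjusted over the list alone). The dendritic cell test gave adjusted p = 4.94e-06, and adjusted p = 0.134 with an estimated correlation. Matrix genes had 19 of 30 higher and 1 lower (23 and 1 adjusted over the list alone), with a median of 1.86. Among them, Mmp13 was at 3.84, Lum at 2.63 and Col6a3 at 2.45. The Mmp13 change is treated as a lower bound, its T2 mean being 4.21. The matrix test gave adjusted p = 2.45e-20, and adjusted p = 0.158 with an estimated correlation. Cell cycle genes had 13 of 27 higher, with the proliferation marker Mki67 at 2.03 and the topoisomerase Top2a at 1.97 (15 adjusted over the list alone). The cell cycle test gave adjusted p = 1.55e-12, and adjusted p = 0.134 with an estimated correlation. Pattern recognition had 5 of 24 higher, with Clec7a at 3.49 (12, and 1 lower, adjusted over the list alone). The pattern recognition test gave adjusted p = 1.28e-05, and adjusted p = 0.414 with an estimated correlation. Complement had 5 of 18 higher (8 adjusted over the list alone). The complement test gave adjusted p = 8.53e-05, and adjusted p = 0.158 with an estimated correlation. Chemokines had 5 of 28 higher, with Ccl8 at 3.66 (9, and 1 lower, adjusted over the list alone). The chemokine test gave adjusted p = 0.000117, and adjusted p = 0.504 with an estimated correlation. Inhibitory receptors and immune regulation had 4 of 20 higher, with Btla at 1.41 and Cd274 at 1.05 (6, and 1 lower, adjusted over the list alone). The immune regulation test gave adjusted p = 0.00224, and adjusted p = 0.134 with an estimated correlation. The calls of 4 more lists ended without T28 replicate 1. These were neutrophil (5 of 20 higher and 1 lower, and 7 and 1 adjusted over the list alone; adjusted p = 0.000912, 0.0861 without the array, and adjusted p = 0.528 with an estimated correlation), interferon gamma response and MHC class II (5 of 20 higher, and 5 and 1 lower adjusted over the list alone; adjusted p = 0.000902, 0.168 without the array, and adjusted p = 0.504 with an estimated correlation), NK and cytotoxic (2 of 13 higher, and 2 and 1 lower adjusted over the list alone; adjusted p = 0.0229, 0.0537 without the array, and adjusted p = 0.296 with an estimated correlation), and adipose (3 of 8 higher, also adjusted over the list alone; adjusted p = 0.0186, 0.168 without the array and 0.0599 without T2 replicate 4, and adjusted p = 0.504 with an estimated correlation).

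Lists of fatty acid oxidation, steroid and drug metabolism, heat shock, acute phase, collecting duct and proximal tubule genes were lower at T28 than at T2. Fatty acid oxidation and peroxisome had 14 of 25 lower, such as the thioesterase Acot1 (-1.98), the peroxisomal enzyme Ehhadh (-1.77) and the lipid-sensing receptor Ppara (-1.13), and 21 adjusted over the list alone, with a median of -0.87. The fatty acid oxidation test gave adjusted p = 1.46e-13, and adjusted p = 0.186 with an estimated correlation. Steroid, bile acid and drug metabolism had 8 of 22 lower (14, and 1 higher, adjusted over the list alone), with a median of -0.58. The steroid and drug metabolism test gave adjusted p = 8.11e-11, and adjusted p = 0.134 with an estimated correlation. Heat shock and ER stress had 6 of 20 lower, with Chac1 at -1.60 and the heat shock protein Hspa1b at -1.35 (11 adjusted over the list alone). The heat shock test gave adjusted p = 1.22e-08, and adjusted p = 0.0764 with an estimated correlation. Acute phase genes had 6 of 23 lower and 1 higher (9 and 2 adjusted over the list alone). The acute phase test gave adjusted p = 0.000249, and adjusted p = 0.414 with an estimated correlation. With the replicate number as a fixed block the acute phase list was not called, and its median was -0.33 instead of -0.79. That fit rests T28 on replicate 1 alone. Collecting duct genes had 4 of 17 lower, with Aqp2 at -1.72 (6 adjusted over the list alone). The collecting duct test gave adjusted p = 0.000211, and adjusted p = 0.504 with an estimated correlation. Proximal tubule genes had 8 of 27 lower and 2 higher, with Pck1 at -2.79 (10 and 3 adjusted over the list alone). The proximal tubule test gave adjusted p = 0.00145, and adjusted p = 0.603 with an estimated correlation. The other 15 lists were not called. Among them were oxidative phosphorylation (0 of 28 called, adjusted p = 0.0804) and glycolysis and hypoxia (1 of 21 higher and 2 lower, adjusted p = 0.225). The cytokine list (adjusted p = 0.316) had a median of 0.10 and a mean of -0.005, coagulation (0.614) a median of -0.12 and a mean of 0.07, erythroid (0.888) a median of -0.13 and a mean of 0.23, and type I interferon (0.772) a median of -0.02 and a mean of 0.006.

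Between the phases, limma called 1257 of 18193 genes, 722 higher and 535 lower at T28, of which 422 and 222 differed at least 2-fold. The count was 531, 813 and 700 without T2 replicates 1, 3 and 4, 774 and 783 without T28 replicates 1 and 6, and 2589, including 1224 of the 1257, without T28 replicate 7. It was 487, including 452 of the 1257, without the arrays with adrenal transcripts. Among genes at or above the median level, 475 were higher and 563 lower, the reverse of the balance over all genes.

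Genes called in both phases included Lcn2, S100a8, S100a9, Cxcl2, Saa3, Cd14, Arg1, Fos and Timp1, all higher. In all, 205 genes were called in both phases, 101 higher in both and 91 lower in both, against 9.68 and 8.35 for independent calls; 8 were higher at T2 and lower at T28 and 5 the reverse, against 7.01 and 11.5. Of the 459 genes called at T2 and not at T28, 253 were also called between the phases, and of the 797 called at T28 and not at T2, 416 were. Across all genes, which are not independent replicates, the changes of the phases had a Pearson r of 0.399 and a Spearman rho of 0.368. Both comparisons share the 3 control arrays, which are too few to split. Their calls are therefore not independent, and the excess of calls in the same direction is not shown to be a shared response. Simulated data with no effect gave a mean r of 0.501 (SD 0.0128 over 100 simulations), with 0 genes called in both. There each gene had the same spread in all groups, and genes were drawn independently. The real median SD was 0.124 in the controls, 0.164 at T2 and 0.235 at T28. The simulations therefore do not give the r or covariance of the real shared controls, and the observed r cannot be judged against them. The covariance was 0.0722, and 0.0221 in the simulations. For the same reason the difference of 0.0501 is not shown to be a shared effect of the phases.

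**Figure D3:**
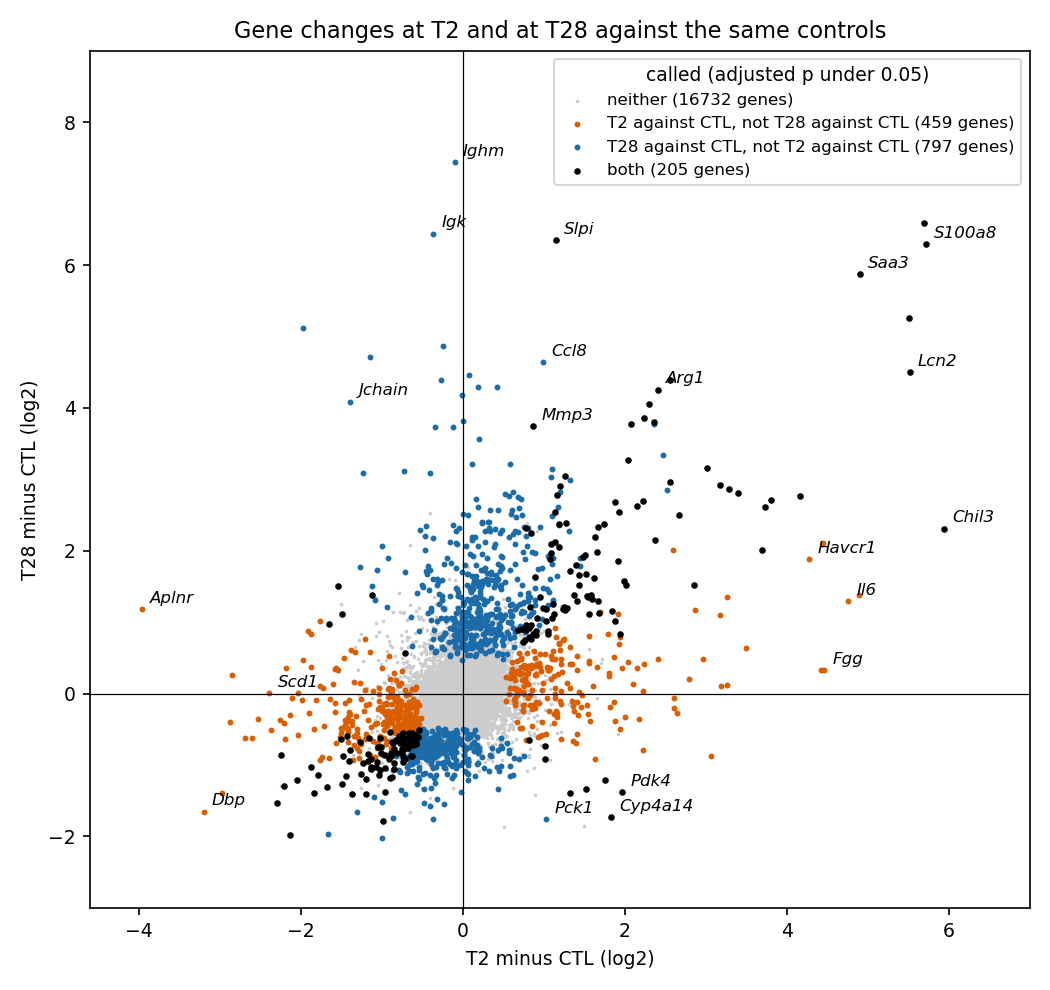
Log2 change of each gene at T2 (horizontal axis) and at T28 (vertical axis) against the same 3 control arrays, coloured by call: 459 genes at T2 and not T28, 797 at T28 and not T2, 205 in both and 16732 in neither. Fga and Fgg lie far right near the horizontal axis and Ighm far up near the vertical axis.

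Several genes of interest were fixed for reporting whatever their result. Tnf, Cxcl1, Ifng, Il10 and Il17a, which encode inflammatory, T cell and regulatory cytokines, were not called in either phase. Their log2 changes at T2 were 0.41, 0.80, 0.02, 0.16 and -0.14 (adjusted p = 0.289, 0.0648, 0.987, 0.830 and 0.706), and at T28 they were 0.42, 0.13, 0.31, 0.29 and -0.04 (0.195, 0.770, 0.570, 0.475 and 0.905). The T cell genes Cd3e, Foxp3, Pdcd1 and Ctla4 had changes of 0.35, 0.29, 0.44 and 0.58 at T28 (adjusted p = 0.240, 0.370, 0.164 and 0.0514) and of -0.07, 0.06, 0.07 and 0.05 at T2, and none was called. Il6 and Havcr1, called at T2, had changes of 1.30 and 1.88 at T28 (adjusted p = 0.141 and 0.119), and Havcr1 differed between the phases by -2.39 at adjusted p = 0.0493, a call lost without any one of CTL replicates 1, 2 and 4, T2 replicates 1, 3 and 4 and T28 replicate 6, and with quantile normalization (adjusted p up to 0.151). Col1a1 had a change of -1.27 at T2 (adjusted p = 0.191) and of 1.77 at T28 (0.0497), the latter call lost with quantile normalization and on leaving out any single array other than T28 replicate 7 (adjusted p up to 0.170). The phosphate transporter Slc34a1 and the loop of Henle protein Umod had changes of -0.31 and 0.06 at T2 and of -0.21 and -0.18 at T28, and Aqp2 had -0.29 at T28, none of them called. The F test called 1695 of 18193 genes as different among the 3 groups; the count was 899, 895, 910 and 943 without CTL replicates 1, 2 and 4 and T2 replicate 1, and 3334 without T28 replicate 7.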

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

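The tests of T28 replicate 7, the comparisons of tubule with other kidney genes, the test of RNA quality at T28 and the test without the arrays with adrenal transcripts were chosen only after the data were seen; the counts over other splits of the arrays were planned. The items below are differences between the phases, given as the log2 change at T28 minus that at T2, each with a call in the direct test.

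The direct test called 1257 genes between T28 and T2. The lists with opposite directions against the controls were extracellular matrix and fibrosis, with a median difference of 1.86, fatty acid oxidation and peroxisome, with -0.87, steroid, bile acid and drug metabolism, with -0.58, and cell cycle, with 0.66. Each was called in 1 direction at T2 and in the other at T28 at the preset correlation, and none was called in either phase with the estimated correlation. Of the 13 genes called in opposite directions in the 2 phases, 5 were lower at T2 and higher at T28, against 11.5 expected from independent calls: Alas2, the first enzyme of heme synthesis in red cells (2.61), Col3a1 (3.04), Lum (2.63), the lymphocyte protein Ms4a4b (2.50) and the Wnt antagonist Sfrp1 (1.27). The other 8 were higher at T2 and lower at T28, against 7.01 expected: Cyp4a14 (-3.56), the glycine-cleaving enzyme Gldc (-2.96), Ntmt1 (-2.86), Pdk4 (-3.35), Reep6 (-1.75), Slc45a3 (-1.47), the sulfotransferase Sult1d1 (-1.93) and the pantetheinase Vnn1 (-2.71). The calls of the phases share the same controls and are not independent, so the expected counts are no measure of an excess or a shortfall. Of the 13, Cyp4a14 alone kept both calls against the controls without each single array and under quantile normalization, centring and the mean of its probe sets. The other 12 lost at least 1 of their calls under some of these, with adjusted p up to 0.580 for Sfrp1 at T28.

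Among genes called at T2, not called at T28 and called between the phases, the differences were -3.51 for Fgb, -3.47 for Il6, -4.14 for Fgg, -2.34 for Saa1, -4.09 for Fga and -2.39 for Havcr1, which were higher at T2. They were 5.15 for Aplnr, 2.47 for Slc22a30, 3.11 for Thrsp, 2.08 for Slc8a1, 1.99 for Hdc and 2.17 for Inmt, which were lower at T2. Among genes called at T28 and not at T2, they were 7.55 for Ighm, 6.80 for Igk, 7.10 for Iglv1, 5.11 for a further kappa variable gene, 5.87 for Igkv8-30 and 3.66 for Ccl8, higher at T28, and -1.03 for Ces2b, -2.79 for Pck1, -1.38 for Abhd3, -1.31 for Slc25a16, -1.16 for the lactate transporter Slc5a8 and -1.35 for Adtrp, lower at T28. For Il6, Igk and the further kappa variable gene the lower group mean was at most 4.46, the highest Y-linked signal. These differences are therefore treated as lower bounds in size. The calls between the phases for Saa1, Havcr1, Hdc, Ces2b, Abhd3 and Adtrp were lost without some single arrays, with adjusted p up to 0.149, 0.151, 0.0578, 0.123, 0.0593 and 0.0899.

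Fits of only the 6 arrays compared, repeated for each of their 10 splits into 3 and 3, gave 1301 calls for T2 against CTL, 377 for T28 against CTL and 531 for T28 against T2 with the real split, and at most 0 with the others, so that 1 of 10 splits gave as many. These splits are too few for a share under 0.05. For the F test over 9 arrays, 100 of the 280 possible splits were used. Of these 1, the real one itself, gave as many calls (1695, against 258 for the highest other). This argues against chance in the allocation of arrays as the source of the count. A share of 1 in 100 is the smallest these splits could give, and whether each array came from a separate animal is not stated.

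T28 replicate 7 lay nearer to the controls than the other T28 arrays, and without it 2652 genes were called instead of 1002. An uninfected kidney under a wrong label is argued against: of 1248 genes called higher at T28 without this array, 73.6% lay above all 3 controls in it, and of 1404 called lower, 68.2% lay below them, and where each control was left out of the fit in turn, 82.6% to 83.5% of the higher genes lay above the other 2 controls in T28 replicate 7 against 32.8% to 38.8% in the control left out (77.6% to 80.9% against 33.6% to 54.1% below them for the lower genes). Lower RNA quality is argued against, as its 3' minus 5' signal gaps of actin (0.987) and Gapdh (0.196) were within the range of the other 8 arrays. Less of the same affected tissue in the piece taken may account for the pattern and remains open. On the linear scale the array showed a median fraction of 0.317 of the change of the other T28 arrays for 95 immune cell genes and of 0.108 for 25 matrix genes. Taken over the genes of this 1 array, which are not independent, the difference was 0.209 (permutation p = 0.00024). Its interval over genes, 0.0649 to 0.294, reaches below the 0.1 that this explanation allows. The demand on the interval was added after the value was seen and turned that reading from excluded to open; a milder or earlier course of infection in this kidney stays open as well, untested.

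Proximal tubule genes were lower at T28 while immune cell genes were higher. A lower share of all kidney cells alike as the whole cause is argued against for the genes of these lists. Podocyte genes had a median change of -0.01 and lay above proximal tubule genes (-0.46) by 0.445 (interval 0.174 to 0.677, permutation p = 0.00081). Intervals and permutation p here and below are over genes, which are not independent, and do not measure the spread between kidneys. On T28 replicates 1, 6 and 7 the podocyte score was -0.25, 0.24 and 0.04, against -0.60, -0.66 and -0.13 for proximal tubule. The mean signal of the podocyte genes was lower (7.94 against 11 on the log2 scale), and low signals can compress changes. Adrenal tissue in some pieces is argued against, since the list was still called lower without CTL replicate 4 and T28 replicate 1 (median -0.33, adjusted p = 3.75e-06). Lower RNA quality cannot be told apart from the group, since the Gapdh gap was larger at T28 than in the controls by 0.307, with every T28 array above every control, while the actin gap, larger by 0.0721, overlapped it. A loss of tubule cells and lower expression within them both stay open, since whole tissue cannot separate them: collecting duct genes fell about as far as proximal tubule genes (median -0.39, a difference of 0.0688 with an interval of -0.281 to 0.221, at a mean signal of 8.5), loop of Henle genes were not called (median -0.18, adjusted p = 0.101, a difference of 0.273 with an interval of -0.00322 to 0.451, permutation p = 0.0147), and the proximal tubule call itself rested on the preset correlation (adjusted p = 0.255 with an estimated correlation).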

How the results depend on the processing

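The alternative without the arrays with adrenal transcripts was chosen after the data were seen; the others were planned. Counts of called genes stayed within 1.5 times the reported ones in all 4 comparisons under quantile normalization, centring, the filter on level, all probe sets, the mean of a gene's probe sets, an intensity trend, a robust prior and the random block. With array weights T2 against CTL gave 1530. With only the groups compared the counts were 1301 (T2), 377 (T28) and 531 (T28 against T2); an added 2-fold threshold gave 337, 496 and 644, by its own construction fewer. The replicate number as a fixed block gave 426 for T2 and 1658 for T28, although arrays of the same number correlated no more than others (0.046, 0.016, -0.021 and -0.043). Without the arrays with adrenal transcripts the counts were 321, 162, 487 and, for the F test, 601; fewer samples alone lower a count. Leaving out 1 array gave 242 to 1012 calls for T2, 312 to 2652 for T28 and 531 to 2589 for T28 against T2, with 0 shared calls changing sign. The F test gave 895 to 3334. The largest counts came without T28 replicate 7. No T28 array enters the difference of T2 from CTL, so its rise to 1012 came from the spread fitted over all groups. For the other comparisons the reason was not tested. Whether more genes were called higher or lower turned under some alternatives: with the filter on level, T28 against CTL had 394 higher and 593 lower in place of 581 and 421. The correlation of the phases' changes ranged from 0.327 to 0.431.

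With an estimated correlation 1, 0 and 0 lists were called at T2, at T28 and between them, in place of 23, 25 and 20; fry called 8, 19 and 13. Centring and the mean of probe sets kept all 68 list calls. Centring was a weak check of the lists, since the array medians were nearly equal before it and camera compares a list with all other genes. The fixed block kept 64 and ended 4. Without the arrays with adrenal transcripts 62 were kept and 6 lost. Without single arrays, each list call was counted once for every array left out, and of these pairs 600 were kept and 12 lost. Of the list results, 2 reversed. Type I interferon between the phases was 0.29 with the fixed block, a fit that rests T28 on replicate 1 alone. The adrenal list at T28 was -0.56 without T28 replicate 1 (adjusted p = 0.0473, and up to 0.946 over its alternatives), ranging up to 0.88 without single arrays. Of 365 calls of named genes, 361 were kept with centring, 346 with quantile normalization and 329 with the mean of probe sets. Without single arrays, each call was counted once for every array left out. Of these pairs of call and array 2669 were kept, 616 lost and 0 reversed. Counted by call, 47 of 111 named calls at T2 were lost without some single array. At T28 59 of 133 were lost in this way, and between the phases 21 of 121. Except where stated, the cause was not tested. Signal over background was judged only against 3 Y-linked genes, so for dim genes a missing call is not shown to be a missing change.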

Other observations

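The families below were named by shared symbol stems after the data were seen, 39 families in each comparison; the clock test was also chosen only after the result was seen, and the test of further glucocorticoid targets was written before its result. A symbol stem can also take in genes of another function, such as Ighmbp2 among the immunoglobulin stems and Gstcd among the Gst genes. Genes of the mitochondrial ribosome (Mrp, 76 genes) were lower in each phase against the same 3 controls, with a median log2 change of -0.34 at T2 (8 lower, 0 higher) and -0.40 at T28 (7 lower, 0 higher), and the Nduf genes (44), subunits and assembly factors of respiratory complex I among them, had medians of -0.33 and -0.39 with 5 and 9 lower. These falls are not independent of each other, since the controls alone can carry part of both, and no value without change was computed for a family. Between the phases the medians were -0.05 for Mrp (adjusted p = 0.273) and -0.03 for Nduf (adjusted p = 0.476), and 0.04 and 0.05 with quantile normalization. The medians of both families against the controls kept their sign with quantile normalization and with centring, as did those of every family given below. Their tests gave adjusted p = 2.28e-12 and 2.69e-14 for Mrp and 9.05e-13 and 8.41e-13 for Nduf at the preset correlation (adjusted p = 0.592 and 0.375, and 0.592 and 0.346, with an estimated correlation). Organic ion transporters of the Slc22a family (21 genes), many of which act in the proximal tubule, had 7 lower at T2 (median -0.78; adjusted p = 2.14e-08) and 3 lower at T28 (median -0.60; adjusted p = 1.35e-05), with adjusted p = 0.592 and 0.379 with an estimated correlation. The Gst genes (21), glutathione transferases for the most part, had 5 lower at T28 (median -0.44; adjusted p = 4.72e-07; adjusted p = 0.145 with an estimated correlation).

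Matrix metalloproteinases (Mmp, 18 genes) had 7 higher at T28 (median 0.87; adjusted p = 1.76e-09), C-type lectins (Clec, 26 genes) 7 higher and 1 lower (median 0.16; adjusted p = 0.000139), and genes with immunoglobulin stems (21 genes) 13 higher (median 3.73; adjusted p = 9.21e-22), each with adjusted p = 0.0751 with an estimated correlation. Between the phases, 14 of the 21 genes with immunoglobulin stems were higher at T28, with a median of 3.81. Probe sets with no symbol or with several, 10092 in all, were tested apart: 91 were called at T2, 95 at T28 and 134 between the phases.

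At T2, the clock gene Dbp fell and several genes induced by glucocorticoids were high, among them Fkbp5 (2.79), Zbtb16 (2.61) and, not called, Tsc22d3 (1.07, adjusted p = 0.0840), which were chosen after their values were seen. A glucocorticoid response at T2 is a hypothesis that fits the values: 12 further targets had a median change of 0.497 with 4 called higher (camera p = 6.99e-09, and p = 0.00138 with an estimated correlation), and a median of -0.84 between T2 and T28, although Cebpd among them is also an acute phase gene. Collection at another time of day cannot be told apart from an effect of infection: a score over 13 clock genes was 0.904 higher at T2 than in the controls, above every control array, but also 0.644 higher at T28, whose titles share the time point of the controls, with T28 replicates 6 and 7 (0.943 and 0.673) above every control and T28 replicate 1 (0.314) below CTL replicate 1 (0.343). The clock score differed between the 6 infected and the 3 control arrays with an exact permutation p of 0.0238 (two-sided, 84 splits), and without Dbp, whose fall prompted the test, the 12 other genes gave scores 0.713 higher at T2 and 0.559 higher at T28 with the same p, while the labels used here give no hour of collection. Inflammation itself may move both gene sets, which was not tested.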
